A study of Mus musculus with 30 samples.

How the data were processed

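RNA sequencing had been carried out on retinal pigment epithelium (RPE) taken from 1 eye of each of 30 male wild-type C57BL/6 mice, aged 10 to 13 weeks, with 5 mice at each of 6 zeitgeber times (ZT): 0, 2, 4, 9, 14 and 19 h. Per the labels, front segment and retina were removed, the remaining eyecup went into RNAlater, and clumps of RPE were later lifted off the choroid with forceps. RNA came from a micro-scale column kit, and single reads of 75 bp were run on a NextSeq instrument, with a stated mean depth of 20 M reads (M: mega). The submitters' processing notes name STAR, Cufflinks, DESeq2 and the mouse build mm10, without versions, roles or order. The values used here are the deposited FPKM (fragments scaled by transcript length and by mapped depth) that the authors computed, 1 value per gene and sample for 51904 Ensembl genes, written with decimal commas. The unit follows from the name of the table, and the reading of the comma was checked on the values: sample totals lie between 700956 and 922481, and low values step in units of 1 read. Raw reads and counts were not used here, so no count-based tool was run. Which annotation the authors used, and how they treated reads shared between genes, is not stated.

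Every value column matched 1 sample through its animal number and eye. Gene positions come from GENCODE M21 on GRCm38, the same assembly as mm10, in which 51625 of the 51904 Ensembl IDs were found. The number of reads behind each sample was estimated from the step between low FPKM values of genes with a single transcript. With 199 bases taken off the exon length, 6178 of 53919 values fell in 1 narrow peak, against at most 2023 with the 4 other lengths tried. This gave 12.5 to 23.0 M reads per sample, and it is an estimate, not a deposited count. At this scale a zero can also be a failed estimate by the quantification tool, so genes listed at 0 are described as such.

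Genes with an FPKM of at least 1 in at least 5 samples were kept (16741 genes), and log2(FPKM + 1) was analysed with limma 3.58.1 in R 4.3.3 with a mean-variance trend. Rhythms were fitted as a 24 h cosine (intercept, cosine and sine of ZT, all 30 samples), tested with limma's moderated F test on both terms; the amplitude is the distance from the fitted mean to the fitted peak on the log2 scale. A second fit with 1 mean per time point gave a moderated F test for any difference among time points, a contrast of day (ZT2, ZT4 and ZT9) against night (ZT14 and ZT19), a contrast of ZT2 against the mean of ZT0 and ZT4, and each step between neighbouring time points. Lights-off at ZT12 is the convention and is not in the labels. All tests are two-sided unless said otherwise, and p values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Where a gene's change is given, its SE comes from this fit, and SD is the spread among the 5 mice of a time point. Tested on simulated data built from the samples' own residuals, the fits recovered known changes as the results state, with 53 false calls in 5 draws for the rhythm and 44 for ZT0 against ZT19. Each draw held 200 changed genes. Over all draws the rhythm test recovered 88, 241 and 322 of them at amplitudes of 0.5, 1 and 1.5. For ZT0 against ZT19 the numbers were 60, 207 and 284 at 2-fold, 4-fold and 8-fold. In both tests the false calls were a larger share of all calls than the threshold of 0.05. With fewer true changes the adjusted threshold is stricter and recovery lower.

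Before the data were examined, 30 gene lists were fixed: core clock, immediate early, phagocytosis of outer segments, lysosome and autophagy, visual cycle, melanogenesis, transport, receptors, secreted factors, cholesterol, lipid oxidation, glycolysis, respiratory chain, heat shock, cold-inducible, endoplasmic reticulum stress, glucocorticoid-responsive, antioxidant, cell cycle, and markers of rods, cones, inner retina, endothelium, stroma, mural cells, melanocytes and Schwann cells, blood, immune cells, lens and skeletal muscle. Lists for surface epithelium (cornea and conjunctiva), oligodendrocytes and mitosis were added after such genes were seen among the abundant or called ones. The p values of these added lists are therefore no independent support. Rhythmic members were counted over all genes and adjusted over the list alone, with Fisher's exact test against the other genes. Lists were tested in each contrast with camera at a preset correlation of 0.01 and, beside it, with an estimated correlation. Camera p values were adjusted over the 30 fixed lists, and separately over the 3 added lists. The mean log2(FPKM + 1) of a list in a sample is its score; scores were tested for a 24 h cosine with 100000 permutations of the times, and ZT0 against ZT19 with an exact permutation test of all 252 splits, whose smallest p is 0.00794. Members of a list are not independent of each other. The rule for named genes was also fixed before: every core clock member, the 10 largest amplitudes past the threshold outside that list, up to 3 members of each other list past the threshold or else the member with the smallest p, and the 5 largest rises and falls of each contrast past the threshold. Predicted genes were counted and not named. Some genes under this rule are counted but not reported here.

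Alternatives were another pseudocount (0.1), no filter or a stricter filter (FPKM of at least 5), median-of-ratios and quantile scaling, no variance trend, robust variances, sample weights, eye side, runs of animal numbers, rod and stroma scores as terms, a threshold of 0.01, added 12 h terms, ranks, fits on the compared time points only, and leaving out each sample in turn. Terms for 5 marker scores (rod, stroma, skeletal muscle, surface epithelium, oligodendrocyte), rescaling without small RNAs, and the same settings for list contrasts, peak times and marker scores were added after seeing the data. Replicate numbers follow the order of deposit only. The other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.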

Results

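The data describe transcript levels through 1 day in samples of mouse RPE, the pigmented cell layer that supports the photoreceptors. The 30 libraries, each from 1 eye of 1 mouse, fall into 6 time points of 5 mice: ZT0, ZT2, ZT4, ZT9, ZT14 and ZT19, where ZT0 is lights-on by convention. The estimated depth was 12.5 to 23.0 M reads per sample (M: mega). Between 16723 and 19374 genes were above 0 in 29 samples, and 12754 in ZT14 replicate 3. That sample listed 557 genes at 0 whose median in the other samples was at least 10 FPKM, against 1 to 23 such genes in the other samples. Samples of the same time point were hardly more alike (median Pearson r = 0.879 across genes) than samples of different time points (median 0.873). RPE transcripts were abundant, with a median of 4251 FPKM for Ttr and 2405 FPKM for Rgr, both of the visual cycle list. Transcripts of other eye tissues varied widely among the samples: the corneal keratin gene Krt12 ranged from 3.42 to 4704 FPKM, the fast muscle gene Mylpf from 828 to 9847 FPKM, and the myelin gene Mobp from 0.166 to 1870 FPKM. Their medians were 2034 FPKM for Krt12, 2018 FPKM for Mylpf and 414 FPKM for Mobp. In a typical sample Krt12 and Mylpf were thus nearly as abundant as Rgr. Which tissue a called transcript came from was not measured.

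The first question was which transcripts followed a day-night rhythm. In the 24 h fit 18 of 16741 genes passed the threshold, and 8 of these were among the 24 measured genes of the core clock list (16 adjusted over the list alone, adjusted p = 6.27e-18 in Fisher's exact test). The clock genes peaked one after another. Nr1d1 (ENSMUSG00000020889, chromosome 11, start 98767932, end 98775333 in mm10), which encodes the repressor REV-ERB alpha, peaked at ZT 7.4 with a standard error of 0.3 h, and its mean level was 14.1 ± 10.5 FPKM at ZT19 and 71.4 ± 8.23 FPKM at ZT9 (mean ± SD, n = 5). Dbp (ENSMUSG00000059824, chromosome 7, start 45705088, end 45710203), a clock output transcription factor, peaked at ZT 9.48, with 47.8 ± 12.7 FPKM at ZT0 and 245 ± 24.4 FPKM at ZT9 (n = 5). Nr1d2 (ENSMUSG00000021775, chromosome 14, start 18204054, end 18239127) peaked at ZT 10.8 and ranged from 18.2 ± 5.79 FPKM at ZT0 to 57.1 ± 4.87 FPKM at ZT9 (n = 5).

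The 3 Period genes, the negative arm of the clock, peaked around the day-night transition. Per2 (ENSMUSG00000055866, chromosome 1, start 91415982, end 91459324) had the largest amplitude of the called genes, 1.82 ± 0.23 on the log2 scale (estimate ± SE, n = 30), peaked at ZT 12.2, and reached 50.2 ± 46.0 FPKM at ZT14 against 1.79 ± 1.02 FPKM at ZT2 (n = 5). Per3 (ENSMUSG00000028957, chromosome 4, start 151003652, end 151044665) peaked at ZT 11.8 with an amplitude of 0.93 ± 0.12, and Per1 (ENSMUSG00000020893, chromosome 11, start 69095217, end 69109960) at ZT 11.5 with an amplitude of 1.00 ± 0.15. Opposite to them, Arntl (ENSMUSG00000055116, chromosome 7, start 113207465, end 113314126), which encodes the clock activator BMAL1, peaked at ZT 23.5 with an amplitude of 1.55 ± 0.15, with 19.5 ± 5.82 FPKM at ZT0 and 2.22 ± 2.06 FPKM at ZT14 (n = 5). Adjusted p over all genes was 3.73e-07 for Arntl, Nr1d1, Nr1d2 and Dbp, 6.33e-05 for Per2, 6.54e-05 for Per3 and 0.00127 for Per1 (limma).

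**Figure D1:**
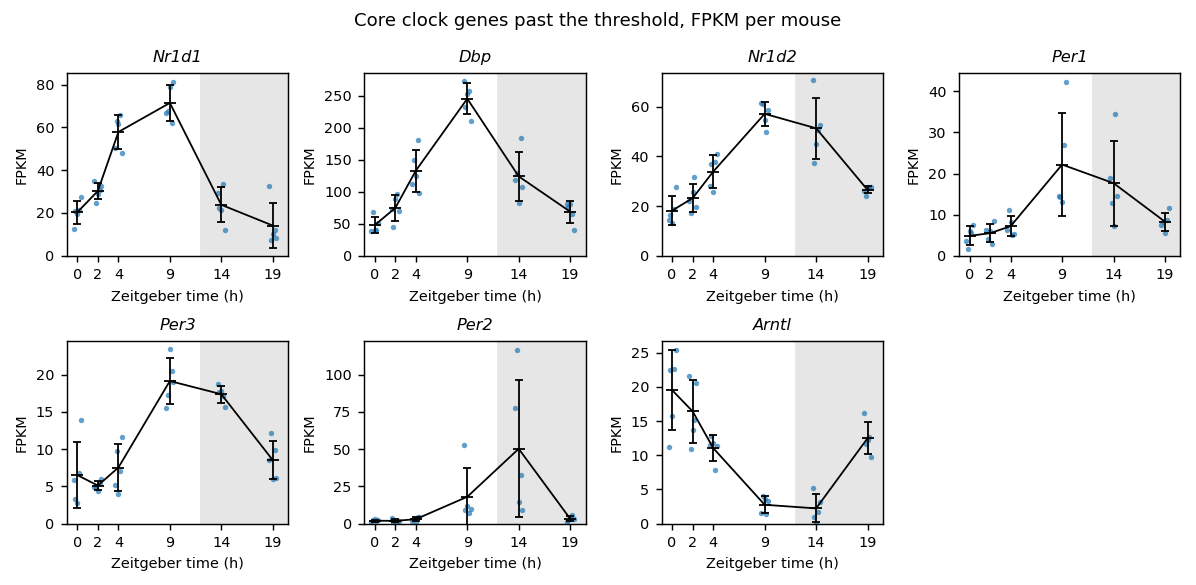
FPKM (vertical axes, linear) of 7 core clock genes past the threshold against zeitgeber time in hours (horizontal axes), with 1 point per mouse, the mean and SD of 5 mice in black, and conventional night in grey. The panels run from Nr1d1, with its highest mean of 71.4 FPKM at ZT9, to Arntl, with its highest mean of 19.5 FPKM at ZT0.

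The other 16 core clock members did not pass over all genes. Their nearest values were Nfil3 (amplitude 0.89, peak ZT 22.4, adjusted p = 0.0672), Npas2 (0.91, ZT 2.1, adjusted p = 0.0745), Ciart (1.51, ZT 8.63, adjusted p = 0.107) and Bhlhe41 (0.46, ZT 13.0, adjusted p = 0.119). Cry2 and Tef had adjusted p values of 0.16 and 0.162. Clock, the partner of BMAL1, had an amplitude of 0.30 ± 0.11 (adjusted p = 0.509), with 25.4 ± 8.33 FPKM at ZT0 and 14.3 ± 3.15 FPKM at ZT14 (n = 5). Cry1 gave 0.54 ± 0.37 (adjusted p = 0.794), and Bhlhe40, Csnk1d, Rora, Rorb, Hlf, Csnk1e and Fbxl21 had adjusted p values from 0.452 to 0.932. In simulated data the rhythm test recovered 26.9% of genes with an amplitude of 0.5, 72.8% at 1 and 94.2% at 1.5, so rhythms of small amplitude were often not detectable with these samples. With 200 changed genes per draw, far more than the real calls, these shares can overstate recovery in the real data.

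The other 10 rhythmic genes lay outside the core clock list, and glucocorticoid-responsive genes were prominent among them. Of the 15 measured genes of the glucocorticoid list, 4 passed the threshold (6 adjusted over the list alone, adjusted p = 1.9e-08 in Fisher's exact test): Tsc22d3, Sgk1, Zbtb16 and Per1, which the core clock list also holds. Tsc22d3 (ENSMUSG00000031431, chromosome X, start 140539528, end 140600659), which encodes the glucocorticoid-induced protein GILZ, peaked at ZT 14.3 with an amplitude of 0.86 ± 0.09 (n = 30, adjusted p = 3.17e-06), with 32.0 ± 7.72 FPKM at ZT2 and 106 ± 13.3 FPKM at ZT14 (n = 5). Sgk1 (ENSMUSG00000019970, chromosome 10, start 21882184, end 21999903), a kinase gene that regulates ion transport, peaked at ZT 14.0 with an amplitude of 0.41 ± 0.06 (adjusted p = 7.74e-04), with 193 ± 26.0 FPKM at ZT2 and 345 ± 49.2 FPKM at ZT14 (n = 5). Zbtb16 (ENSMUSG00000066687, chromosome 9, start 48654297, end 48836222) peaked at ZT 13.8 with an amplitude of 0.76 ± 0.13 (adjusted p = 0.0117, and 0.108 with rod and stroma scores as terms, with a lowest amplitude of 0.67 in any setting). Fkbp5, another member, had an amplitude of 0.51 ± 0.16 and a fitted peak at ZT 14.6 (adjusted p = 0.452).

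Other genes with peaks in the early night were Angptl7, a secreted angiopoietin-like factor gene (ENSMUSG00000028989, chromosome 4, start 148495183, end 148500460, ZT 14.8, amplitude 1.03 ± 0.14, adjusted p = 2.23e-04), and Fmo1, a flavin-containing monooxygenase gene (ENSMUSG00000040181, chromosome 1, start 162829561, end 162866610, ZT 15.2, amplitude 0.91 ± 0.12, adjusted p = 1.74e-04). Angptl7 measured 27.9 ± 6.81 FPKM at ZT0 and 117 ± 48.9 FPKM at ZT14, and Fmo1 25.3 ± 10.5 FPKM at ZT2 and 101 ± 37.9 FPKM at ZT14 (n = 5). Ctgf, a matricellular growth factor gene of the secreted list, peaked at ZT 12.6 (amplitude 0.75 ± 0.14, adjusted p = 0.0202), Tspan4, a tetraspanin gene, at ZT 12.5 (0.60 ± 0.08, adjusted p = 2.23e-04), and the cyclin D1 gene Ccnd1 of the cell cycle list at ZT 9.22 (0.46 ± 0.08, adjusted p = 0.0171). Leo1, a subunit gene of the PAF1 transcription elongation complex, peaked at ZT 22.2 (0.57 ± 0.10, adjusted p = 0.0202), and the matrix protease gene Mmp14 at ZT 2.09 (0.36 ± 0.07, adjusted p = 0.0404). The calls of Ctgf, Leo1, Ccnd1 and Mmp14 were lost in 3, 5, 2 and 21 of the 30 fits that left out 1 sample. Their highest adjusted p values were 0.0635 (without ZT14 replicate 4), 0.0812 (without ZT9 replicate 3), 0.0812 (without ZT9 replicate 3) and 0.132 (without ZT14 replicate 5). With rod and stroma scores as terms Ctgf, Leo1 and Mmp14 also lost their calls (adjusted p = 0.0873, 0.0873 and 0.138), as did Ctgf and Mmp14 with the 5 marker scores (adjusted p = 0.0659 and 0.102). Without the variance trend Ccnd1 and Mmp14 lost their calls (adjusted p = 0.0531 and 0.0874), as did Mmp14 with animal number runs as a block (adjusted p = 0.0555). Leo1 lost its call after rescaling without small RNAs (adjusted p = 0.0798). The lowest amplitude in any setting was 0.50 for Leo1, 0.32 for Mmp14, 0.40 for Ccnd1 and 0.48 for Ctgf, so those of Leo1, Mmp14 and Ccnd1 stayed near their values above. Of the 18 rhythmic genes 13 peaked between ZT8 and ZT16, where permuted times placed 17.3% of top genes in the bin from ZT8 to ZT12 and 16.9% in the bin from ZT12 to ZT16.

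**Figure D2:**
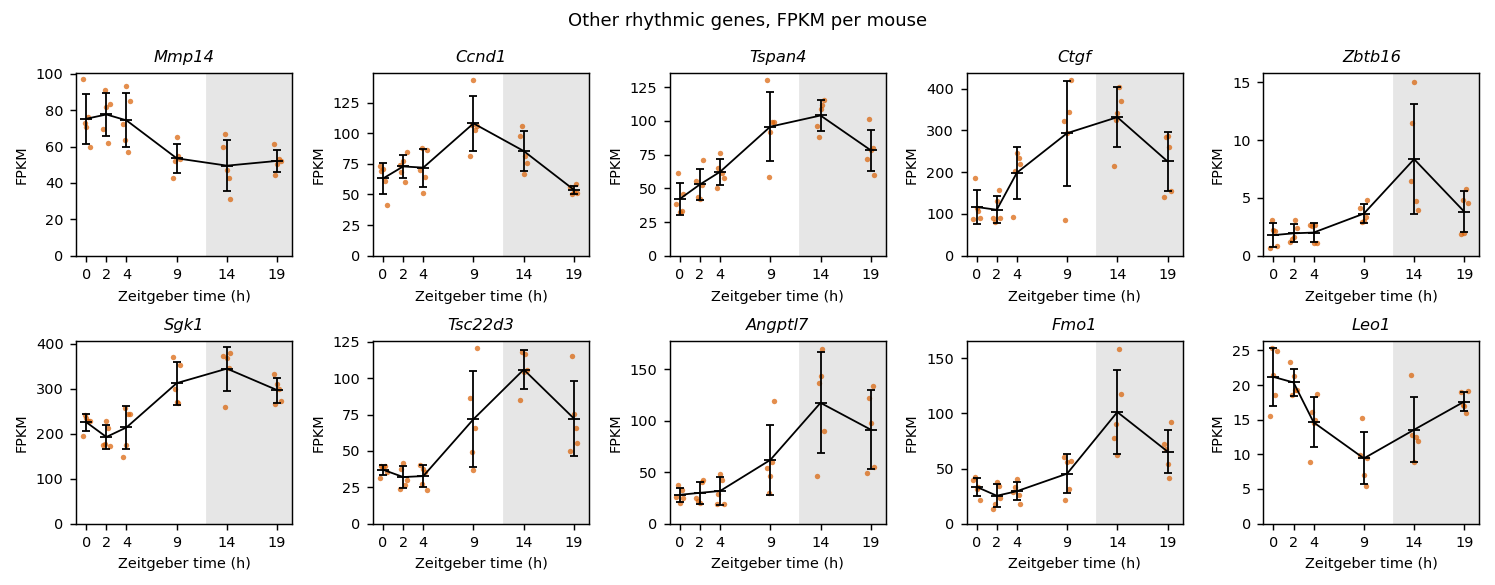
FPKM (vertical axes, linear) of the 10 rhythmic genes outside the core clock list against zeitgeber time in hours (horizontal axes), with 1 point per mouse, the mean and SD of 5 mice in black, and conventional night in grey. Tsc22d3, Fmo1 and Angptl7 have their highest means at ZT14, at 106, 101 and 117 FPKM.

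Lists of RPE functions held few or no rhythmic genes. Only 18 of 16741 genes passed, so a count of 0 in a short list is near the share over all genes. It is no result about these functions. In limma 1466 of the 16741 genes had an unadjusted p below 0.05 in the rhythm test, where chance gives 837. The unadjusted counts of the lists stand against that share. None of the 21 phagocytosis genes passed over all genes (1 adjusted over the list alone, Axl, with an amplitude of 0.52 ± 0.12, a fitted peak at ZT 13.8 and adjusted p = 0.16), although 4 had an unadjusted p below 0.05 in limma. None of the 13 measured visual cycle genes passed (1 alone, Lrat, 0.51 ± 0.12, ZT 12.2, adjusted p = 0.175; 3 unadjusted). The counts over all genes and adjusted over the list alone were 0 and 0 for lysosome and autophagy (26 measured, smallest p for Rubcn, adjusted p = 0.486), melanogenesis (16, Mlph, 0.486), transport (22, Car14, 0.386) and receptors (12, Adora2b, 0.547), with 2, 2, 4 and 1 unadjusted. The secreted list had 1 of 14 (Ctgf, 2 alone, adjusted p = 0.12 in Fisher's exact test) and the cell cycle list 1 of 15 (Ccnd1, 3 alone, adjusted p = 0.12).

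Metabolic and stress lists had no member past the threshold over all genes in limma. Adjusted over the list alone, the 3 cold-inducible genes, 2 of 19 heat shock genes (smallest p for Dnaja1, adjusted p = 0.126) and 1 of 20 endoplasmic reticulum stress genes (Sdf2l1, amplitude 0.69 ± 0.14, ZT 21.6, adjusted p = 0.0672) passed, with 3, 3 and 7 genes at an unadjusted p below 0.05. The counts adjusted over the list alone were 0 for the immediate early (Nr4a3, adjusted p = 0.458), cholesterol (Mvd, 0.298), lipid oxidation (Acot1, 0.52), glycolysis (Ldha, 0.486), respiratory chain (Ndufv1, 0.567) and antioxidant lists (Sod2, 0.537), with 4, 6, 2, 2, 1 and 1 genes unadjusted. Among the tissue marker lists, 2 of 14 stroma genes (Pdgfra, adjusted p = 0.326) and 1 of 10 melanocyte and Schwann cell genes (Cdh19, 0.338) passed adjusted over the list alone. The rod (Rcvrn, 0.727), cone (Opn1mw, 0.788), inner retina (Gad1, 0.685), endothelium (Eng, 0.463), mural (Notch3, 0.571), blood (Hba-a2, 0.644), immune (Tyrobp, 0.533), lens (Bfsp2, 0.524) and skeletal muscle lists (Pvalb, 0.528) had 0, with 0, 0, 0, 1, 0, 0, 4, 2 and 2 unadjusted. Brackets give the gene with the smallest p and its adjusted p over all genes. Of the lists added afterwards, mitosis had 14 of 28 genes adjusted over the list alone (Pbk, 0.16), while surface epithelium (Calml3, 0.54) and oligodendrocyte (Opalin, 0.85) had 0, with 17, 2 and 0 unadjusted.

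As whole lists, the mean levels of 5 of the 30 lists followed a 24 h cosine by permutation. The glucocorticoid score peaked at ZT 13.6 (amplitude 0.21 log2, adjusted permutation p = 0.0021) and without its 4 called members had an amplitude of 0.03 (permutation p = 0.822). The remaining members had differing fitted peaks, which can cancel in a mean. The core clock score peaked at ZT 10.3 (0.27, adjusted permutation p = 0.00435) and the secreted score at ZT 12.9 (0.24, adjusted permutation p = 0.0172). The phagocytosis score peaked at ZT 14.1 with a small amplitude of 0.08 (adjusted permutation p = 0.005), and 0.06 without Axl (permutation p = 0.0107). Its highest value was that of ZT14 replicate 3, without which the amplitude was 0.07 (adjusted permutation p = 0.0163). The score of the cold-inducible RNA-binding protein genes Cirbp, Rbm3 and Srsf5 peaked at ZT 5.92 (0.24, adjusted permutation p = 0.0139). None of these 5 scores was fitted with tissue marker scores as terms, so the tissue mix was not accounted for.

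A test without an assumed shape found 12 genes that differed among the 6 time points. They were Dbp, Arntl, Nr1d1, Nr1d2, Per2, Per3, Tsc22d3, Tspan4, Fmo1, Angptl7 and Sgk1, which also passed the 24 h fit, and the mitotic kinase gene Pbk (adjusted p = 0.00231), which did not (adjusted p = 0.16). Dbp had the smallest adjusted p, 9.62e-06. These names outside the rule were taken after their values were seen.

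The contrast of day (ZT2, ZT4 and ZT9) with night (ZT14 and ZT19) called 2 genes higher by day and 3 higher at night. In limma 1765 of 16741 genes had an unadjusted p below 0.05 in this contrast. By day Nr1d1 was higher by 1.53 ± 0.18 log2 (estimate ± SE, adjusted p = 5.51e-05), and Pbk by 1.89 ± 0.33 (adjusted p = 0.0133). Tsc22d3 fell by 1.06 ± 0.16 (adjusted p = 0.0022), Fmo1 fell by 1.33 ± 0.20 (adjusted p = 0.0022) and Angptl7 fell by 1.37 ± 0.24 (adjusted p = 0.0128) from night to day. The glucocorticoid list as a group was lower by day (camera adjusted p = 2.06e-04, and adjusted p = 0.0274 with an estimated correlation). The cholesterol list, with 11 of 23 genes higher at an unadjusted p below 0.05, was higher by day (camera adjusted p = 3.75e-07), but not past the threshold with the estimate (adjusted p = 0.168 with an estimated correlation). Markers of other tissues moved in the same contrast. By day 10 of 18 surface epithelium genes were higher at an unadjusted p below 0.05 (camera adjusted p = 3.55e-11, and adjusted p = 0.0826 with an estimated correlation), and 6 of 13 skeletal muscle genes were lower (camera adjusted p = 1.35e-04, and adjusted p = 0.455 with an estimated correlation). Of the 30 lists 15 were called with the preset correlation and 1 with the estimate. The call of Pbk was lost without ZT14 replicate 2 (adjusted p = 0.05), with rod and stroma scores as terms, and with the 5 marker scores (adjusted p = 0.492), while its change was at least 1.72 log2 in every setting.

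Around lights-on, when rods shed the tips of their outer segments and RPE engulfs them, no step was detected for single genes. ZT2 against ZT0, ZT4 against ZT2, and ZT2 against the mean of ZT0 and ZT4 each gave 0 genes in limma, with 502, 566 and 421 genes at an unadjusted p below 0.05. Chance gives 837. Among the 21 phagocytosis genes the change from ZT0 to ZT2 ranged from -0.36 (Scarb1) to 0.63 (Tub) log2 with a median SE of 0.30, and among the 26 lysosome and autophagy genes from -0.50 (Tfeb) to 0.47 (Mcoln1) with a median SE of 0.22. Visual cycle genes ranged from 0.03 (Rdh5) to 0.58 (Rdh11). The surface epithelium score had a mean of 8.59 ± 0.34 at ZT2 and 7.49 ± 1.44 at ZT4 (SD, n = 5). With the preset correlation 5, 14 and 5 lists were called in these 3 contrasts in that order, and 0 with the estimate. The median SE over all genes was 0.39 log2 for a step between neighbouring time points, so changes of this size could not be resolved.

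Between ZT4 and ZT9 the core clock list rose as a group (camera adjusted p = 7.56e-07, and adjusted p = 0.00993 with an estimated correlation), with 9 members higher and 1 lower at an unadjusted p below 0.05. Arntl, with 11.0 ± 1.90 FPKM at ZT4 and 2.75 ± 1.24 FPKM at ZT9 (n = 5), had the smallest p (adjusted p = 0.436). No gene passed the threshold in limma, and 582 had an unadjusted p below 0.05. Of the 30 lists 11 were called with the preset correlation, and the core clock list alone with the estimate. Tissue markers moved in the same step. The blood and immune lists were lower at ZT9 (medians of -0.967 and -0.361 log2, camera adjusted p = 2.73e-05 and 5.08e-04, and adjusted p = 0.181 and 0.211 with an estimated correlation).

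From ZT9 to ZT14 no gene passed in limma, with 1128 genes at an unadjusted p below 0.05. Nr1d1 came nearest (adjusted p = 0.0596), with 71.4 ± 8.23 FPKM at ZT9 and 23.8 ± 8.2 FPKM at ZT14 (n = 5). The glucocorticoid, lysosome and autophagy, and melanocyte and Schwann cell lists were higher as groups at ZT14 (camera adjusted p = 0.0338 for each), and their calls were lost with the estimate (adjusted p = 0.345, 0.416 and 0.416 with an estimated correlation). The oligodendrocyte list, a marker of carried-over tissue, was higher with them (median 1.48 log2, camera adjusted p = 0.00129, and adjusted p = 0.476 with an estimated correlation). Of the 30 fits that left out 1 sample, 5 called 1 or 2 genes.

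From ZT14 to ZT19 Arntl rose by 2.32 ± 0.35 log2 (adjusted p = 0.00673), from 2.22 ± 2.06 to 12.5 ± 2.34 FPKM, and Per2 fell by 3.15 ± 0.54 (adjusted p = 0.0229), from 50.2 ± 46.0 to 3.24 ± 1.81 FPKM (n = 5). These were the 2 genes called, and 1611 had an unadjusted p below 0.05. The respiratory chain list was higher at ZT19, with 20 of 48 genes higher at an unadjusted p below 0.05 (camera adjusted p = 3.57e-13, and adjusted p = 0.362 with an estimated correlation), as was the skeletal muscle list, with 7 of 13 (camera adjusted p = 4.49e-06, and adjusted p = 0.382 with an estimated correlation), and the blood list, with 4 of 5 (camera adjusted p = 0.00382, and adjusted p = 0.382 with an estimated correlation). The surface epithelium list was lower at ZT19, with 11 of 18 genes lower (camera adjusted p = 3.05e-13, and adjusted p = 0.103 with an estimated correlation). Per2 lost its call in 5 of the 30 fits without 1 sample (ZT14 replicates 1 and 2, ZT19 replicates 1, 2 and 5), with a highest adjusted p of 0.117 without ZT19 replicate 2. With a pseudocount of 0.1 neither gene passed. In the main fit 11 lists were called with the preset correlation against 0 with the estimate.

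The step from ZT19 to ZT0 called 6 genes higher at ZT0 and 1 lower, and the genes that rose included mitotic genes. Pbk (ENSMUSG00000022033, chromosome 14, start 65805837, end 65817822) rose most among the called genes (log2 change 3.76 ± 0.51 with the pseudocount, adjusted p = 8.55e-04), from listed at 0 in all 5 samples at ZT19 to 13.4 ± 5.44 FPKM at ZT0 (n = 5). The size of the Pbk change depends on the pseudocount, and it lay between 3.48 and 6.98 log2 over all settings. Plk1, a mitotic kinase gene (ENSMUSG00000030867, chromosome 7, start 122159439, end 122169873), rose by 2.37 ± 0.44, and Kif15, a mitotic kinesin gene (ENSMUSG00000036768, chromosome 9, start 122951046, end 123018733), by 3.50 ± 0.68. Kif15 was listed at 0 in 4 of 5 samples at ZT19, so the size of its change depends on the pseudocount: with 0.1 it was 6.12 for Kif15 and 3.80 for Plk1, and neither passed. Rapgefl1 (ENSMUSG00000038020, chromosome 11, start 98836785, end 98853697) rose by 2.22 ± 0.41. Ccnf, the cyclin F gene, taken after its value was seen, rose by 1.88 ± 0.36, and Cgrrf1 (ENSMUSG00000055128, chromosome 14, start 46832125, end 46854193) fell by 0.98 ± 0.19. Adjusted p was 0.0471 for Plk1, Kif15, Rapgefl1, Ccnf and Cgrrf1, and 2171 genes had an unadjusted p below 0.05.

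Markers of other tissues moved with the same step. The surface epithelium score, from a list added after the data were seen, was 8.74 ± 0.44 at ZT0 and 6.45 ± 0.54 at ZT19 (SD, n = 5, exact permutation test, adjusted p = 0.0437), and Krt12 measured 2800 ± 448 and 337 ± 368 FPKM. All 18 genes of that list were higher at ZT0 at an unadjusted p below 0.05 (camera adjusted p = 4.46e-24, and adjusted p = 0.00789 with an estimated correlation). Both values were adjusted over the 3 added lists alone, not over the 30 fixed lists. Because such genes were seen before the list was made, its p values here are no independent support. Of the mitosis list 22 of 28 genes were likewise higher at an unadjusted p below 0.05. That list was added because of genes called in this step, so no p value is given for it. It was part of the adjustment: exact permutation p values were adjusted over the 30 fixed and 3 added lists together. The skeletal muscle score was lower at ZT0 (7.23 ± 0.42 against 8.57 ± 0.70, n = 5, exact permutation test, adjusted p = 0.0437). So was the visual cycle score (7.63 ± 0.30 against 8.36 ± 0.16, n = 5, exact permutation test, adjusted p = 0.0437), with 11 of 13 genes lower at an unadjusted p below 0.05 (camera adjusted p = 1.22e-09, and adjusted p = 0.156 with an estimated correlation). Neither score followed a 24 h cosine past the threshold (adjusted permutation p = 0.549 for skeletal muscle and 0.5 for visual cycle). The fall of the visual cycle score was not particular to that list. The transport, secreted, respiratory chain, glucocorticoid, stroma and immune scores were also lower at ZT0 (exact permutation test, adjusted p = 0.0437 for each). With the same adjusted p, the immediate early and cholesterol scores were higher at ZT0. Of the 30 lists fixed before, 17 were called with the preset correlation and 0 with the estimate. In simulated data this step recovered 17.3% of 2-fold, 65.3% of 4-fold and 84.3% of 8-fold changes. Each draw held 200 changed genes, far more than were called in the real data, so real recovery can be lower. With 1 sample left out the count ranged from 1 (without any of 9 samples) to 107 (without ZT14 replicate 3, a sample outside the comparison). Of these 30 fits Kif15 lost its call in 18, Rapgefl1 in 14, Plk1 in 13, Cgrrf1 in 20 and Pbk in 0, and with the 5 marker scores as terms no gene was called. In that fit the changes of Pbk (3.48 log2), Kif15 (3.30) and Cgrrf1 (-1.065) stayed near their values above. Those of Plk1 (0.70), Rapgefl1 (1.14) and Ccnf (0.88) became smaller.

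**Figure D3:**
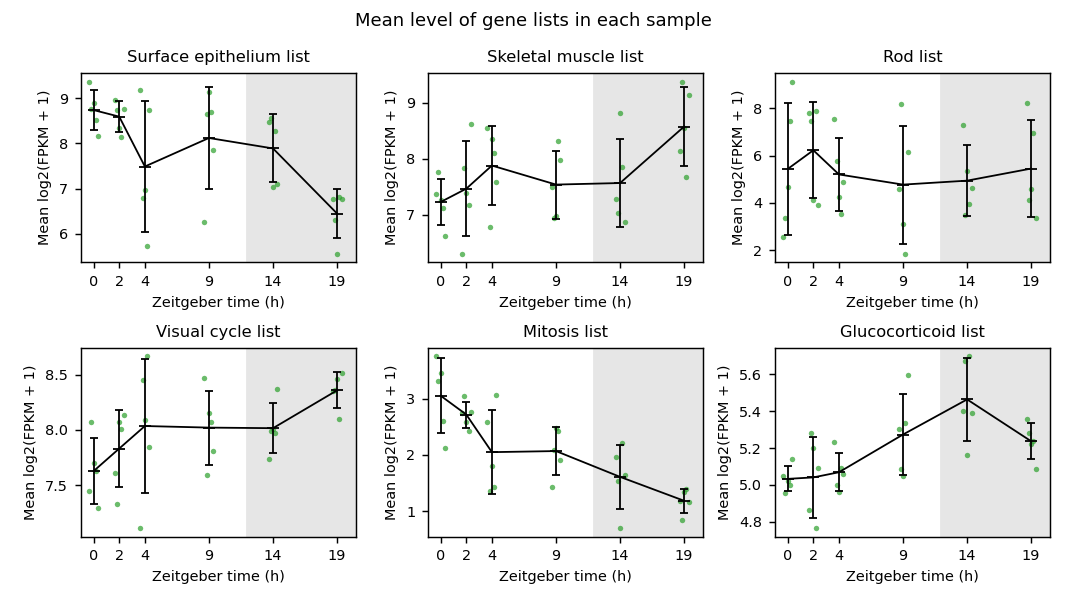
Mean log2(FPKM + 1) of the genes of 6 lists (vertical axes) against zeitgeber time in hours (horizontal axes), with 1 point per mouse, the mean and SD of 5 mice in black, and conventional night in grey. The surface epithelium score has its lowest mean at ZT19 (6.45) and the skeletal muscle score its highest (8.57), the glucocorticoid score is highest at ZT14 (5.46), and the rod score spreads widely at every time point.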

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

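In this part, all tests of explanations were chosen after the result was seen, except the counts from other splits of the samples. The test of glucocorticoid signalling used the members not called and a window around ZT14, so it too followed the rhythm result. Of 198 groups of 5 samples examined over 33 values, 11 (5.56%) held 1 sample far from the other 4, where chance gives about 1 in 20. Genes above 0 numbered 19374 in ZT0 replicate 4, against 17605 in the nearest sample of its time point. In ZT14 replicate 3 the number was 12754, against 17143 in the nearest. The relative depth of ZT14 replicate 1 was 0.834, against 1.12 to 1.17 in the other 4. The lens score of ZT14 replicate 2 was 3.64, against at most 1.24. Per2 measured 52.6 FPKM in ZT9 replicate 1, against at most 11.6. Nr1d1 measured 32.6 FPKM in ZT19 replicate 1, against at most 12.1. Ctgf measured 186 FPKM in ZT0 replicate 2, against at most 114. In ZT4 replicate 1 Ctgf measured 92.2 FPKM, against at least 202. Sgk1 measured 260 FPKM in ZT14 replicate 2, against at least 346. Kif15 measured 16.8 FPKM in ZT14 replicate 1, against at most 3.43. In ZT19 replicate 5 Kif15 measured 3.63 FPKM and was listed at 0 in the other 4.

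Counts of called genes were set beside 100 assignments of the same samples to the groups, the real one included. The real 18 rhythmic genes were reached by 2 of 100, with up to 90 in another assignment, so the structure of the samples alone can give many calls. The 12 genes that differ among time points were reached by the real assignment alone (1 of 100, highest other 3), as were the 5 day against night genes (1 of 100, highest other 1) and the 7 genes of ZT0 against ZT19 (1 of 100, highest other 4). The 2 genes of ZT19 against ZT14 were reached by 9 of 100 (highest other 3), so chance is not excluded for that count. For the 5 contrasts with 0 genes this count is no test, since every assignment gives at least 0. Their highest others were 3 (ZT2 against ZT0 and ZT4), 144 (ZT2 against ZT0), 2 (ZT4 against ZT2), 355 (ZT9 against ZT4) and 1 (ZT14 against ZT9).

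Of the 15 measured glucocorticoid-responsive genes, Tsc22d3, Sgk1 and Zbtb16 peaked near ZT14 and Per1 at ZT 11.5, while the score of the other 11 had an amplitude of 0.03 log2 (permutation p = 0.822). Those 11 were the members not called, and opposed fitted peaks can cancel in their mean. Fkbp5 (0.51 ± 0.16, ZT 14.6) and Klf9 (0.30 ± 0.10, ZT 13.0) stood against Lcn2 (0.76 ± 0.32, ZT 0.71), for example. For the called members other than Per1, the mix of the 5 scored tissues is argued against as the whole cause. With the 5 marker scores as terms these members kept a median of 0.9 of their amplitude. Of the 3, 2 stayed past the threshold, and Zbtb16 did not (limma, adjusted p = 0.0959). Other tissue scores, such as endothelium and immune, were not terms. For members not called with peaks near ZT14, the ratio of amplitudes was 0.26 for Mt1 and 0.12 for Mt2. It was 1.38 for Fkbp5, 0.8 for Klf9 and 1.79 for Dusp1. A rhythm in glucocorticoid signalling was tested on the 11 members that were not called, of which 5 (45.5%) peaked within 4 h of ZT14, against 30.5% of 16184 other genes (one-sided Fisher's exact p = 0.221). This leaves open whether the hormone or another signal of the early night drives the called genes.

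Genes higher at ZT0 than at ZT19 included mitotic genes. Fewer reads at ZT19 are argued against, since the relative depth was 0.929 ± 0.095 at ZT19 and 0.879 ± 0.12 at ZT0 (SD, n = 5, exact permutation p = 0.524). With the surface epithelium score as a term, the median rise of the 6 genes went from 2.46 to 1.31 log2 (a ratio of 0.53, where slopes from the other time points gave a change of 1.1) and 0 of 6 passed, but Pbk kept 2.93 ± 0.64 of 3.76 ± 0.51 (SE, adjusted p = 0.364), where its slope gave 0.90. The mitosis score without called genes (24 genes of a list chosen because of this pattern) kept a 24 h cosine beyond its relation with the surface epithelium score, with an amplitude of 0.38 and a peak at ZT 1.1 (permutation p = 0.00112). Because of that choice, this p value is no independent support for daily timing. The rise could come from more surface epithelium at ZT0, from daily timing of its cell division, or from both, and these samples leave that open.

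The mean score of the visual cycle list was higher at ZT19 than at ZT0, although single members had other peaks (Lrat measured 241 FPKM at ZT14 and 200 FPKM at ZT19). From ZT19 to ZT0 the skeletal muscle score changed by -1.35 log2 and the surface epithelium score by 2.29, so other tissues did not all rise. This cannot exclude a lower share of RPE at ZT0, because more surface epithelium alone would lower that share. The melanogenesis and transport scores also changed, by -0.27 and -0.25 log2. With the surface epithelium score as a term the visual cycle difference went from -0.73 to -0.12 log2 (a ratio of 0.16), which leaves more surface epithelium at ZT0 open. Set against the melanogenesis and transport lists, whose genes other tissues also express, the score still differed by -0.47 log2 (n = 5, exact permutation p = 0.0159), which leaves a rhythm within RPE open. ZT0 and ZT19 held the lowest and highest visual cycle means, and the exact p does not account for that choice. Over all time points the visual cycle score gave no 24 h cosine past the threshold (permutation p = 0.221, adjusted permutation p = 0.5).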

How the results depend on the processing

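The fits with 5 marker scores, the rescaling without small RNAs, and all alternatives for list contrasts, peak times and marker scores were added after the data were seen. Of 47 named gene results 26 kept the same call under every alternative, and of 31 called ones 16. With 1 sample left out, the counts ranged over 14 to 24 rhythmic genes, 11 to 16 genes that differ among time points, 4 to 7 for day against night, 2 to 3 rhythmic lists, 11 to 16 peaks from ZT8 to ZT16, 65 to 88 list contrasts and 4 to 6 marker scores, and stayed at 0 for ZT2 against ZT0, ZT4 against ZT2 and ZT2 against ZT0 and ZT4. They were 0 to 1 for ZT9 against ZT4 (1 without ZT14 replicate 3), 0 to 2 for ZT14 against ZT9 (2 without ZT14 replicate 1), 1 to 5 for ZT19 against ZT14 (5 without ZT14 replicate 4 or ZT19 replicate 4, 1 without ZT19 replicate 1, 2 or 5) and 1 to 107 for ZT0 against ZT19. The last was 107 without ZT14 replicate 3, 79 without ZT9 replicate 1, and 21, 14 and 13 without ZT4 replicates 5, 1 and 4, and 1 without any of 9 samples. For ZT0 against ZT19 (7 genes) other settings gave 311 with only the time points compared, 286 with sample weights, 15 with quantile scaling, 4 with median-of-ratios scaling or no trend, 2 with no filter, 1 with a pseudocount of 0.1, eye side, rod and stroma scores or a threshold of 0.01, and 0 with 5 marker scores. For ZT19 against ZT14 (2 genes) they gave 8 with eye side, 1 with no filter or 0.01, and 0 with a pseudocount of 0.1, 5 marker scores or only the time points compared. For ZT14 against ZT9 (0 genes) they gave 1 with no filter, an FPKM of at least 5, median-of-ratios or quantile scaling, eye side, animal number runs, or rod and stroma scores. For ZT9 against ZT4 (0 genes) they gave 1 with quantile scaling or sample weights and 2 with 5 marker scores. No filter gave 1 gene for ZT2 against ZT0 and ZT4 and 2 for ZT2 against ZT0, where 5 marker scores gave 1. Sample weights gave 19 genes that differ among time points, ranks gave 8 rhythmic genes, and 0.01 gave 3 day against night genes. List contrasts (81) numbered 52 at 0.01, 17 with 5 marker scores and 2 with the estimated correlation. The phase of Csnk1e, not called in either fit, turned with 5 marker scores (amplitude 0.102 log2). With these scores 23 genes were rhythmic, 14 of them among the 18. Apart from fewer samples and stricter thresholds, the cause was not tested. No paired analysis was possible because each mouse gave 1 sample. Depth limits low genes, where 1 read is a visible step in FPKM.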

Other observations

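The cold-inducible RNA-binding protein genes, which follow body temperature in other tissues, followed a 24 h cosine as a group (adjusted permutation p = 0.0139). Cirbp measured 117 ± 18.1 FPKM at ZT4 and 87.1 ± 24.9 FPKM at ZT19, Rbm3 79.9 ± 13.7 FPKM at ZT9 and 48.6 ± 19.1 FPKM at ZT19, and Srsf5 162 ± 25.6 FPKM at ZT2 and 114 ± 17.1 FPKM at ZT14 (n = 5). None passed over all genes (adjusted p = 0.476, 0.479 and 0.225). In the same order their fitted peaks differed, at ZT 5.59, 8.21 and 2.61. Rbm3 still measured 74.3 ± 24.7 FPKM at ZT14 (SD, n = 5). Without Srsf5 the score of the other 2 kept its cosine (amplitude 0.29, peak ZT 7.1, permutation p = 0.00575).

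Reading the time of each sample from the 24 core clock genes, with that sample left out, gave a median absolute difference of 0.5 h from its label, and 28 of 30 samples lay within 2 h. Over 99 permuted assignments of the times the median was 5.8 h and the lowest 3.2 h. ZT19 replicate 1 was read 6.7 h from its label, at ZT 19.9 without Nr1d1, and at ZT 20.3 from the 10 other rhythmic genes, which had been chosen with all samples. With those 10 genes the other 29 samples had a median difference of 1.1 h, and 25 lay within 3 h. Left eyes numbered 3, 1, 5, 2, 4 and 1 of 5 at ZT0, ZT2, ZT4, ZT9, ZT14 and ZT19, so eye side and time are partly confounded. An interaction of eye side with the 24 h terms gave 0 genes in limma, with 1033 at an unadjusted p below 0.05. Small RNAs made up 14.2% (ZT19 replicate 5) to 26.8% (ZT2 replicate 2) of all FPKM.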
